A study of Mus musculus with 12 samples.

How the data were processed

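Poly-A RNA of epididymal primary adipocytes from C57BL/6N mice was sequenced in 12 libraries on a HiSeq4000, with TruSeq mRNA libraries made from RNA with a RIN above 7, per the labels' protocols. The groups (3 libraries each) were taken from the sample labels, and the table's columns were matched to them by the age and genotype in their names. Per the submitters' processing notes, HISAT2 2.1.0, HISAT, Bowtie2 and StringTie 1.3.4d were used on mouse genome mm10, with no role or order given for each tool. The deposited table by the authors gives an estimated count of reads and an FPKM value for each of 36779 transcripts in each library. The estimated counts are whole numbers that are not scaled for depth, and the deposited FPKM values were used as an alternative only. Totals per library ran from 45935795 to 61125366 estimated reads. A line of the table was empty in the file used and is not analysed here, and the table holds no mitochondrial transcripts.

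Estimated counts were summed per gene to 24531 genes and scaled by TMM (edgeR 4.0.16, R 4.3.3). Genes kept by filterByExpr, 15059, were tested with the edgeR quasi-likelihood F-test in a fit of all 12 libraries with a mean per group. The common biological coefficient of variation was 24.6%, with 8 residual and 2.89 prior degrees of freedom. Comparisons were AKO against WT at each age, old against young in each genotype, and the difference of the genotype effects between ages. P-values are two-sided and adjusted by Benjamini-Hochberg within each comparison, and a gene with an adjusted p under 0.05 counts as called. Gene lists, 39 in number, covered CREB target genes, adipocyte and metabolic pathways, immune and matrix genes and markers of other cell types. They were tested with camera on voom values (limma 3.58.1) with a preset correlation of 0.01, adjusted over the 38 lists with at least 5 measured members, and again with a correlation estimated per list and with fry. Lists, comparisons, tests, the rule for naming genes and all alternatives except 1 were fixed before the data were examined.

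The rule names Crtc2 first, then the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap and whose mean is at least 1 CPM, then up to 4 members of each list with the smallest p, and for the interaction the 10 genes with the smallest p. Unnamed gene models were passed over, and not every gene the rule gives is printed. Genes named outside the rule were chosen after their values were seen: Crtc1, Crtc3, Pik3r2, Zfp467, Morf4l1b, Zfp965, Kng1, Akr1b7, Crisp1 and genes of the testis, and for a second comparison Lum, Morf4l1-ps1, Dusp4, Fbn1 and Lyz2. CPM values are means ± SD over 3 libraries. Fold changes against a group with 0 reads are lower bounds against a floor of 3 reads over the group, which covers counting error only.

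Data were simulated with each gene drawn on its own at its estimated spread, and the changed genes had a mean of at least 1 CPM. Neither genes that move together nor libraries unlike the rest of their group were simulated, so the rates may not hold in the real libraries. On the simulated data the test found 53.7% of genes changed 2-fold and 95.5% of those changed 4-fold in the young genotype comparison. For the interaction it found 26.9% and 81.8%, and each comparison had 3 to 8 false calls. For 1.5-fold changes it found 1.49% to 13.4%, so small changes are mostly out of reach with 3 libraries per group. Alternatives were DESeq2 size factors (RLE), the DESeq2 1.42.0 Wald test, limma-voom, other filters on low counts, transcripts not summed, limma-trend on log2(FPKM + 1), the replicate number as a block, fits of only the groups compared, a fold threshold and each library left out in turn. Leaving out old WT replicate 3 and young WT replicate 1 together was chosen after seeing the data. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used to read the table and draw figures.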

Results

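RNA from primary adipocytes of mouse epididymal fat was sequenced in 12 libraries. The labels put 3 libraries in each of 4 groups: young (3 months) and old (18 months) mice, each either wild type with floxed Crtc2 (WT) or with an adipocyte-specific Crtc2 knockout (AKO). Crtc2 is a coactivator of CREB, the transcription factor that answers cyclic AMP signals such as those of fasting and of beta-adrenergic receptors. The comparisons ask what losing Crtc2 in adipocytes does to gene expression at each age, what ageing does in each genotype, and whether the genotype effect depends on age. Each library held 45935795 to 61125366 estimated reads, and 15059 of 24531 genes had enough reads to be tested. Fold changes below are log2 values ± SE from the edgeR quasi-likelihood fit, with n = 3 libraries per group and p-values adjusted by Benjamini-Hochberg. The p-values measure the spread between libraries, since the labels do not say whether each library came from a separate mouse. On the first principal component, which held 50.6% of the variance, old WT replicate 3 lay at 99.8, beyond the 68.5 and 64.7 of the other old WT libraries. On the second (12.8% of the variance) young WT replicate 1 lay at 21.4, against -44.1 and -41.7 for the other young WT libraries, and old WT replicate 3 at -43.0, against -5.03 and 2.35. These 2 libraries are said below to stand apart.

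Crtc2 (chromosome 3, 90254281 to 90264125, mm10) was higher in the libraries labelled AKO, although the label names a knockout of this gene. Young libraries labelled AKO had 7751, 15024 and 15248 estimated reads of Crtc2, against 2684, 3567 and 4256 in young WT. Old libraries labelled AKO had 9179, 9977 and 9144, against 2918, 2891 and 2521 in old WT. This was 248 ± 73.5 CPM (read counts scaled to library size, mean ± SD) against 66.8 ± 12.8 in young mice, a log2 difference of 1.89 ± 0.21, adjusted p = 0.00729 (edgeR). In old mice it was 155 ± 5.11 against 49.0 ± 3.29 CPM, a log2 difference of 1.66 ± 0.21, adjusted p = 0.0124 (edgeR). The table gives 1 transcript for Crtc2 and 1 value for its whole length, so the table cannot show whether exons were deleted. Because Crtc2 goes against the labels, AKO and WT mean the groups as labelled throughout, and each direction drawn between them is that of the labels. Without old AKO replicate 2 or 3 the old difference was 1.64 (adjusted p = 0.0741) and 1.71 (adjusted p = 0.0691, edgeR), and with the 6 young libraries fitted alone the young difference was 1.90 (adjusted p = 0.118, edgeR). The related coactivators Crtc1 and Crtc3 did not pass the test in either age: Crtc1 averaged 17.2 CPM in young AKO and 16.9 in young WT, and Crtc3 averaged 27.4 and 28.6 CPM.

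**Figure D1:**
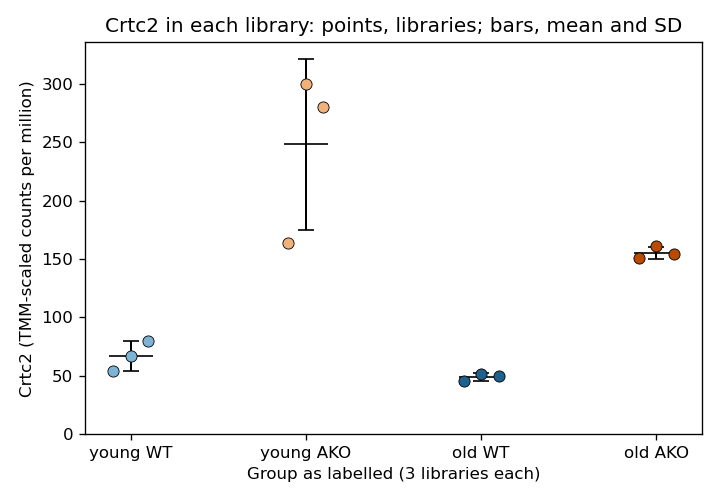
Crtc2 in TMM-scaled CPM (vertical axis) in the 4 groups as labelled (horizontal axis); each point is a library, and bars show the mean and SD of 3 libraries. All 6 libraries labelled AKO lie above all 6 labelled WT.

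In young mice, some genes of connective tissue and vessels were lower in the libraries labelled AKO and some of the mitochondrial respiratory chain higher, while 0 gene lists were called with an estimated correlation. The fibroblast and progenitor markers Cd248 (-1.17 ± 0.17, adjusted p = 0.0226) and Cd34 (-1.16 ± 0.23, adjusted p = 0.0433) fell. So did Fbn1, which encodes a microfibril protein (-1.38 ± 0.23, adjusted p = 0.0290), and Loxl2, a collagen cross-linking enzyme (-1.33 ± 0.21, adjusted p = 0.0290, all edgeR). The respiratory chain subunits Cox7b (0.52 ± 0.09, adjusted p = 0.0290) and Cox5b (0.52 ± 0.10, adjusted p = 0.0433) rose, as did Acot2, a mitochondrial acyl-CoA thioesterase (0.51 ± 0.09, adjusted p = 0.0296). A lower share of cells other than adipocytes was not tested as a source of these rises. Gsta4, a glutathione transferase that clears lipid peroxidation products, rose from 31.5 ± 7.79 to 102 ± 18.4 CPM (1.69 ± 0.19, adjusted p = 0.00729). By the edgeR test 28 genes were higher and 120 lower in young AKO, 148 in all, and 2947 genes had an unadjusted p under 0.05.

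Among the other largest rises were the zinc finger gene Zfp949 (1.53 ± 0.19), the MAP kinase phosphatase Dusp4 (0.96 ± 0.15), the membrane protein gene Pmp22 (0.93 ± 0.15), Ly6h (1.07 ± 0.18), the matrix gene Sned1 (0.77 ± 0.14) and Txnl4b (0.73 ± 0.12). Morf4l1-ps1, a copy of Morf4l1 (0.76 ± 0.07), also rose, but shares sequence with its parent, so its level is uncertain. Zfp973 had no reads in young WT and 3.14 ± 0.305 CPM in young AKO, at least 163-fold higher against a floor of 3 reads over the group. Its level is uncertain, because near-identical copies can share its reads. Among the largest falls were the serine protease Prss23 (-2.64 ± 0.48), the protease inhibitor Wfdc1 (-2.41 ± 0.45), the ephrin receptor Epha1 (-2.32 ± 0.33), the cartilage matrix gene Cilp (-2.25 ± 0.40), Cyb5r2 (-2.24 ± 0.40), the kinase Camkk1 (-2.04 ± 0.32), Tmod2 (-1.98 ± 0.30), Hmcn1 (-1.97 ± 0.32) and the matricellular gene Cyr61 (-1.95 ± 0.26). Adjusted p for these genes lay between 0.00134 and 0.0376 (edgeR).

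Of the 44 nuclear genes of oxidative phosphorylation, 5 rose and 0 fell, or 41 when adjusted over the list alone. The median log2 fold change of this list was 0.36 (camera adjusted p = 1.62e-26, adjusted p = 0.231 with an estimated correlation). None of the 22 genes of the tricarboxylic acid cycle passed over all genes tested, but 19 rose when adjusted over the list alone (median 0.36, camera adjusted p = 8.32e-12, adjusted p = 0.231 with an estimated correlation). In the list for fatty acid and triglyceride synthesis the counts were 0 and 10 of 26 (median 0.68, camera adjusted p = 5.47e-07, adjusted p = 0.352 with an estimated correlation). Over the list alone 0 passed without young WT replicate 1 or 2 or young AKO replicate 1 or 3, with the lowest median, 0.50, without young AKO replicate 1, and young AKO replicate 2 had a lower mean of centred log2 CPM over the list (0.161) than young WT replicates 2 and 3 (0.252 and 0.343). Matrix genes fell in 5 of 37 (12 over the list alone; median -0.54, camera adjusted p = 8.33e-07, adjusted p = 0.259 with an estimated correlation), with a median of -0.27 and -0.33 without young WT replicate 1 or 2. Lists of markers of endothelial, stromal, mesothelial, smooth muscle and immune cells had medians below 0, with few members called, while testis germ cell markers had a median of 0.40 and skeletal muscle markers one of 0.03. Endothelial markers had a median of -0.93, with 1 of 21 fallen (Sox17, -1.48 ± 0.26, adjusted p = 0.0296, edgeR). Adjusted over the list alone 17 fell (camera adjusted p = 2.47e-12, adjusted p = 0.306 with an estimated correlation). Progenitor and fibroblast markers had a median of -0.80, with 2 of 23 fallen and 11 over the list alone (camera adjusted p = 1.21e-05, adjusted p = 0.231 with an estimated correlation). The median of mesothelial markers was -1.14 (1 of 17 fallen, 1 over the list alone; adjusted p = 0.470 with an estimated correlation), and without young WT replicate 1 it was -0.52. Smooth muscle and pericyte markers had a median of -0.89 (1 of 16 fallen, 7 over the list alone; adjusted p = 0.231 with an estimated correlation). Macrophage markers had a median of -0.89 (0 of 28 fallen, 0 over the list alone; adjusted p = 0.509 with an estimated correlation). T and NK cell markers had one of -1.29 (0 of 16 fallen, 3 over the list alone; adjusted p = 0.231 with an estimated correlation), and B and plasma cell markers one of -1.20 (0 of 16 fallen, 0 over the list alone; adjusted p = 0.231 with an estimated correlation). The tissue dissociation response, genes that respond to the preparation of cells, had a median of -0.28 with 0 of 26 called (1 lower over the list alone; camera adjusted p = 1.96e-05, adjusted p = 0.334 with an estimated correlation). Of the 22 genes listed beforehand as CREB and CRTC targets, 0 passed over all genes tested and 6 fell when adjusted over the list alone (median -0.38, camera adjusted p = 0.00397, adjusted p = 0.344 with an estimated correlation).

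The young genotype count moves with single libraries: it was 465, 8 and 320 without young WT replicate 1, 2 or 3, 48 and 5 without young AKO replicate 1 or 3, 74 and 447 without old WT replicate 1 or 3, and 17 without old AKO replicate 2. By other tests it was 1369 (DESeq2), 9 (limma-voom) and 17 (limma-trend on FPKM). It was 27 with transcripts not summed per gene, 54 with the replicate block and 4 with the 6 young libraries fitted alone. With old WT replicate 3 and young WT replicate 1 both left out, an alternative chosen after seeing the data, it was 861. Without young AKO replicate 2 it was 197, with 112 higher and 85 lower, so most called genes were then higher.

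In old mice, genes of macrophages, antigen presentation and cell division were lower in the libraries labelled AKO. Of 28 macrophage markers, 24 fell and 0 rose, and 27 fell when adjusted over the list alone, with a median of -2.22 (camera adjusted p = 4.85e-17, adjusted p = 0.194 with an estimated correlation). They include the complement genes C1qa (-1.91 ± 0.30, adjusted p = 0.0187) and C1qc (-2.01 ± 0.35, adjusted p = 0.0187), the mannose receptor Mrc1 (-1.87 ± 0.32, adjusted p = 0.0187) and the lysozyme gene Lyz2 (-2.65 ± 0.46, adjusted p = 0.0187, all edgeR). The largest falls include Gdf3, a growth factor of the TGF-beta family (-5.11 ± 1.12), and the interleukin receptor Il7r (-4.84 ± 0.89). Genes known from myeloid cells are also among them. Mmp12, a macrophage elastase, went from 238 ± 261 to 11.0 ± 4.11 CPM (-4.44 ± 0.81). Gpnmb went from 544 ± 729 to 21.9 ± 12.6 (-4.64 ± 1.04) and Atp6v0d2, a proton pump subunit, from 72.3 ± 89.4 to 3.10 ± 1.19 (-4.54 ± 0.88). The SDs of these genes in old WT are wide, and without old WT replicate 3, which stands apart, the macrophage median was -1.48 with 17 of 28 called. Without old AKO replicate 1, 2 or 3 the median was -2.30, -2.27 and -2.08, and 0 of 28 were called over all genes tested (26, 26 and 25 over the list alone). By the edgeR test 122 genes were higher and 779 lower in old AKO, 901 in all, and 3320 had an unadjusted p under 0.05.

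MHC class II genes, which present antigen, fell in 12 of 14 members (13 adjusted over the list alone; median -1.93, camera adjusted p = 5.98e-12, adjusted p = 0.176 with an estimated correlation), among them Cd74 (-1.89 ± 0.30) and H2-Ab1 (-1.90 ± 0.32). Inflammatory cytokines and NF-kappaB targets fell in 11 of 35 (16 over the list alone; camera adjusted p = 1.55e-08, adjusted p = 0.176 with an estimated correlation), led by Il1b (-3.58 ± 0.57), Tnf (-3.25 ± 0.52) and Il1rn (-3.58 ± 0.59). Proliferation genes fell in 13 of 26 (24 over the list alone; camera adjusted p = 6.52e-11, adjusted p = 0.284 with an estimated correlation), including the mitotic kinase Cdk1 (-2.65 ± 0.52) and Top2a (-2.64 ± 0.54). Matrix genes fell in 10 of 37 (16 over the list alone; camera adjusted p = 1.97e-06, adjusted p = 0.223 with an estimated correlation), among them Lum, which encodes lumican (-1.61 ± 0.17, adjusted p = 0.00538, edgeR), and Fn1, fibronectin (-1.70 ± 0.32). Progenitor and fibroblast markers fell in 7 of 23 (13 over the list alone; median -0.94, camera adjusted p = 3.78e-07, adjusted p = 0.170 with an estimated correlation). Endothelial markers had a median of -0.52 with 0 of 21 called and 20 below 0 (camera adjusted p = 0.000368, adjusted p = 0.423 with an estimated correlation). Medians were -0.99 for T and NK cell markers (2 of 16 fallen), -1.13 for B and plasma cell markers (3 of 16) and -0.98 for neutrophil markers (2 of 6). They were -0.64 for mesothelial (1 of 17), -0.49 for mast cell (0 of 11) and -0.335 for smooth muscle markers (0 of 16). Camera called these lists lower with the preset correlation, none with an estimated one. With each library left out in turn, the camera call was kept in 4 of 12 fits for smooth muscle and 10 of 12 for mast cell markers. Of 23 genes in the senescence list 5 fell, among them the lamin gene Lmnb1 (-1.49 ± 0.28) and Mmp12, which is also in the macrophage list. Over the list alone 6 fell (median -0.48, camera adjusted p = 0.000698, adjusted p = 0.162 with an estimated correlation). Members were not sorted by the direction they take in senescence, so this is not read as less senescence.

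Some genes of insulin action and of lipolysis were higher in old AKO. Hexokinase Hk2 (0.90 ± 0.12, adjusted p = 0.0175), the insulin receptor substrate Irs1 (0.73 ± 0.13, adjusted p = 0.0187) and the insulin-responsive glucose transporter Slc2a4 (0.54 ± 0.14, adjusted p = 0.0435) rose by the edgeR test. Of 28 adipocyte identity and PPARG target genes, 2 rose (7 over the list alone; median 0.40, camera adjusted p = 3.78e-07, adjusted p = 0.176 with an estimated correlation). In insulin signalling and glucose use 4 of 28 genes rose, or 5 over the list alone (camera adjusted p = 0.00488, adjusted p = 0.192 with an estimated correlation). The median of this list was 0.07, with 9 of 28 members below 0. The beta-adrenergic receptor Adrb3 (0.93 ± 0.22), the adenylyl cyclase Adcy6 (0.45 ± 0.10) and the lipid droplet protein Plin1 (0.55 ± 0.14) rose. They are the 3 called of 24 lipolysis genes, with a list median of 0.23 and 5 members below 0. Over the list alone 5 were higher and 1 lower (camera adjusted p = 0.000927, adjusted p = 0.225 with an estimated correlation). A lower share of other cells, left open below, was not tested as a source of these rises. In the list for branched-chain amino acid catabolism, Bckdhb of the dehydrogenase complex rose (0.74 ± 0.14, adjusted p = 0.0187, edgeR), 1 of 25 over all genes and 10 over the list alone (median 0.32, camera adjusted p = 8.17e-08, adjusted p = 0.226 with an estimated correlation). The clock genes Per2 (1.01 ± 0.22), Per3 (1.10 ± 0.25) and Tef (0.95 ± 0.25) rose, 3 of 20 (8 higher and 2 lower over the list alone; camera adjusted p = 0.000457, adjusted p = 0.162 with an estimated correlation). The largest rises were Gsta4 (1.82 ± 0.19, adjusted p = 0.00559, edgeR), Crtc2 and Zfp949 (1.43 ± 0.19), followed by the orphan receptor Gpr152 (1.41 ± 0.32), the transcription factor Sox9 (1.22 ± 0.20), the metalloreductase Steap2 (1.17 ± 0.30), Adgrg2 (1.14 ± 0.24) and Bnc2 (1.13 ± 0.27). Of the CREB and CRTC targets, 4 of 22 fell, over all genes and over the list alone: the phosphodiesterase Pde4b (adjusted p = 0.0291), the nuclear receptors Nr4a2 (-1.06 ± 0.25) and Nr4a3 (-1.47 ± 0.38), and Rgs2 (-2.20 ± 0.51) (camera adjusted p = 0.00518, adjusted p = 0.284 with an estimated correlation).

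Without old WT replicate 3 the median of proliferation genes was -0.78 with 3 of 26 called (17 over the list alone), and that of MHC class II genes -1.44 with 10 of 14 called. Without old AKO replicate 1, 2 or 3, 0 proliferation, MHC class II, cytokine, insulin signalling, lipolysis or clock genes of these lists were called over all genes tested, and 1 gene each of the matrix and progenitor lists. The old genotype count was 387 without old WT replicate 3, and 12, 5 and 4 without old AKO replicate 1, 2 or 3. It was 1911 by DESeq2, 205 with the 6 old libraries fitted alone, 16 (8 higher and 8 lower) with transcripts not summed per gene and 12 with the replicate block. With old WT replicate 3 and young WT replicate 1 both left out, it was 519.

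In mice labelled WT, genes of immune, fibroblast and mesothelial cells were higher with age and genes of adipocyte metabolism lower. A changed share of cells other than adipocytes was not tested as a source of these differences. Macrophage markers rose in 23 of 28 members (26 over the list alone; median 2.61, camera adjusted p = 7.61e-11, adjusted p = 0.326 with an estimated correlation), including Cd209f (2.70 ± 0.24, adjusted p = 0.000442) and C1qa (2.50 ± 0.31, adjusted p = 0.00160, both edgeR). The chemokine Ccl8 rose by 3.99 ± 0.31, adjusted p = 0.000314 (edgeR). The senescence marker Cdkn2a, an inhibitor of cyclin-dependent kinases, rose by 2.29 ± 0.35, adjusted p = 0.00413 (edgeR). Glycerol-phosphate acyltransferase Gpam, which starts triglyceride synthesis, fell (-1.72 ± 0.24, adjusted p = 0.00312), as did Hk2 (-1.18 ± 0.12, adjusted p = 0.000621) and the adipose triglyceride lipase gene Pnpla2 (-0.93 ± 0.20, adjusted p = 0.00972, all edgeR). By the edgeR test 2140 genes were higher and 1319 lower in old WT, and of these 1508 and 193 changed at least 1 log2 unit.

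Branched-chain amino acid catabolism fell in 15 of 25 genes (21 lower and 1 higher over the list alone; median -0.45, camera adjusted p = 3.43e-09, adjusted p = 0.276 with an estimated correlation), for example Dbt (-0.79 ± 0.12) and Acadsb (-0.84 ± 0.16). Adipocyte identity and PPARG target genes fell in 10 of 28 (11 over the list alone; camera adjusted p = 4.86e-05, adjusted p = 0.276 with an estimated correlation), including Plin4 (-0.85 ± 0.16) and the adipogenic factor Cebpa (-0.54 ± 0.11). The CREB and CRTC family fell in 6 of 14 (7 lower and 1 higher over the list alone; camera adjusted p = 0.00948, adjusted p = 0.276 with an estimated correlation), with the kinase Sik2, which phosphorylates CRTC proteins, at -1.10 ± 0.13, adjusted p = 0.00137 (edgeR). Crtc2 itself did not pass (-0.45 ± 0.20, adjusted p = 0.129, edgeR). Of 22 CREB and CRTC targets, 6 rose and 2 fell (7 and 3 over the list alone; camera adjusted p = 0.115, adjusted p = 0.518 with an estimated correlation). MHC class II genes rose in 12 of 14 (13 over the list alone; camera adjusted p = 2.33e-07, adjusted p = 0.312 with an estimated correlation). Proliferation genes rose in 21 of 26 (25 over the list alone; camera adjusted p = 8.57e-07, adjusted p = 0.400 with an estimated correlation). Progenitor and fibroblast markers rose in 14 of 23 and fell in 2 (16 and 3 over the list alone; camera adjusted p = 4.25e-05, adjusted p = 0.276 with an estimated correlation). Mesothelial markers rose in 10 of 17 (15 over the list alone; camera adjusted p = 2.17e-06, adjusted p = 0.400 with an estimated correlation).

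Among the largest rises in old WT were the kinase Alpk2 (5.60 ± 1.03), the muscle calcium-release protein Trdn (5.56 ± 1.03), the desmosome protein Pkp1 (5.29 ± 1.12), Gdf3 (5.24 ± 1.14), the sperm protein gene Crisp2 (4.53 ± 1.16), the proton channel Otop1 (4.43 ± 0.94) and Dhrs9 (4.27 ± 0.84). Among the largest falls were the adhesion gene Chl1 (-6.06 ± 1.47), the xenobiotic-metabolising Cyp2f2 (-5.03 ± 1.06), the angiogenic factor Angpt1 (-3.76 ± 0.64), Zyg11a (-3.72 ± 0.79) and Cyp2b10 (-3.40 ± 0.75). Serpina3k (-5.56 ± 1.19) also fell, but it is 1 of a cluster of near-identical genes that can share reads, so its level is uncertain. Without old WT replicate 3 the median of proliferation genes was 0.96, with 7 of 26 called (19 over the list alone). Mesothelial calls were 2 of 17 without young WT replicate 2 or 3, and 4 and 3 without old WT replicate 2 or 3. The age count in WT, 3459, was 1516 without young WT replicate 3 and 1898 without old WT replicate 3. It was 1059 with the 6 WT libraries fitted alone and 1640 when transcripts were not summed per gene.

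In mice labelled AKO, genes of the respiratory chain were lower with age and markers of mesothelial and endothelial cells higher. Here too a changed share of cells other than adipocytes was not tested as a source. Oxidative phosphorylation genes fell in 34 of 44 (40 over the list alone; median -0.39, camera adjusted p = 2.63e-16, adjusted p = 0.388 with an estimated correlation), among them Cox7b (-0.52 ± 0.09, adjusted p = 0.00516) and Cyc1, cytochrome c1 (-0.69 ± 0.13, adjusted p = 0.00819, both edgeR). In the tricarboxylic acid cycle 16 of 22 fell (19 over the list alone; camera adjusted p = 1.11e-08, adjusted p = 0.388 with an estimated correlation). In fatty acid and triglyceride synthesis 10 of 26 fell (18 over the list alone; camera adjusted p = 1.57e-06, adjusted p = 0.441 with an estimated correlation), including Pnpla3 (-1.57 ± 0.29) and the carbohydrate-response factor Mlxipl (-1.04 ± 0.19). Without young AKO replicate 1 the median of the last list was -0.60, with 4 called. Mesothelial markers rose in 16 of 17 (17 over the list alone; median 2.39, camera adjusted p = 1.13e-07, adjusted p = 0.426 with an estimated correlation). Endothelial markers rose in 14 of 21 (18 over the list alone; median 0.99, camera adjusted p = 8.35e-08, adjusted p = 0.426 with an estimated correlation). Macrophage markers rose in 9 of 28 (9 over the list alone; median 0.94, camera adjusted p = 0.000540, adjusted p = 0.592 with an estimated correlation). These changes were not particular to AKO. In WT with age, oxidative phosphorylation genes fell in 3 of 44 (median -0.163, camera adjusted p = 1.11e-05). The tricarboxylic acid cycle fell in 8 of 22 in WT (median -0.342, camera adjusted p = 6.99e-06). Fatty acid and triglyceride synthesis fell in 8 of 26 in WT (median -0.515, camera adjusted p = 5.45e-06). Camera also called endothelial markers higher with age in WT. None was called in WT with an estimated correlation. By the edgeR test 1573 genes were higher and 1197 lower in old AKO than in young AKO.

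The endothelial gene Vwf (1.89 ± 0.28, adjusted p = 0.00363) and the progenitor markers Cd248 (1.62 ± 0.17, adjusted p = 0.000638) and Col14a1 (2.59 ± 0.41, adjusted p = 0.00461, all edgeR) rose. The chemokines Ccl8 (3.61 ± 0.32) and Cxcl13 (4.94 ± 0.85), and the heat shock gene Hspb1 (1.44 ± 0.15) were all higher in old AKO. Crtc2 fell with age in the libraries labelled AKO (-0.68 ± 0.20, adjusted p = 0.0404, edgeR). Trdn, Nkain2 and Pkp1 had no reads in young AKO and were at least 384-fold, 130-fold and 90.1-fold higher in old AKO against the floor of 3 reads over the group. Other large rises were the glycine receptor subunit Glrb (6.15 ± 1.68), the integrin Itgad (5.50), the lipase Lipf (4.62 ± 1.14) and the choline transporter Slc5a7 (4.49 ± 1.31). The collagen Col3a1 (-1.40 ± 0.16), the complement protease Masp1 (-3.39 ± 0.80), the laminin Lama1 (-3.06 ± 0.79), Angpt1 (-2.81 ± 0.61), Itm2a (-2.64 ± 0.38) and the clock gene Bhlhe40 (-1.62 ± 0.21) fell, with Serpina3f (-3.84 ± 0.67), which is uncertain as a member of the same cluster as Serpina3k. The matrix list as a whole went the other way from Col3a1. Its mean of centred log2 CPM over 37 members was -0.392, -0.69 and -0.69 in young AKO replicates 1, 2 and 3. In old AKO it was 0.025, 0.131 and -0.085. Camera called this list with the preset correlation, also in 12 of 12 fits with a library left out, but not with an estimated one. Of 22 CREB and CRTC targets, 6 rose and 4 fell (8 and 5 over the list alone; camera adjusted p = 0.165, adjusted p = 0.592 with an estimated correlation). The count of 2770 was 835 without young AKO replicate 3 and 734, 1213 and 1517 without old AKO replicate 1, 2 or 3. It was 1019 when transcripts were not summed per gene.

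**Figure D2:**
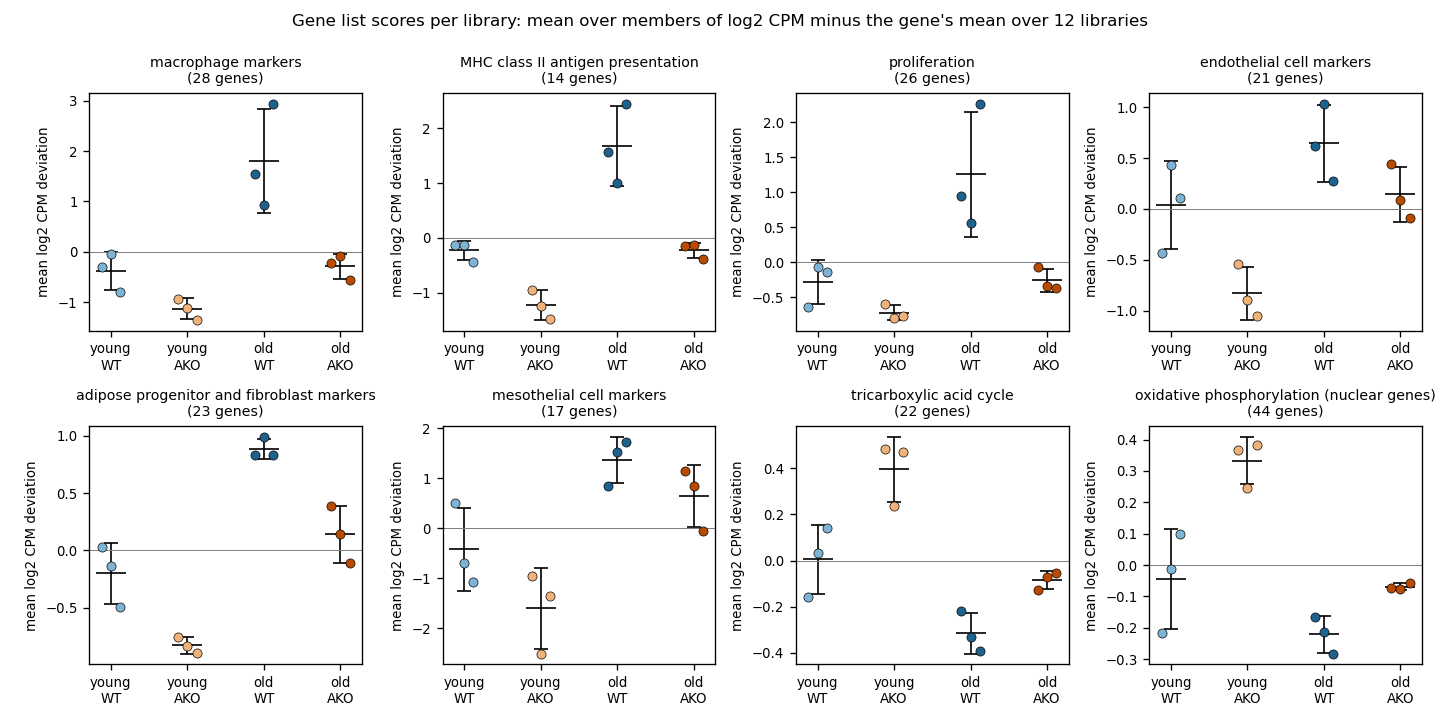
Mean log2 CPM of the measured members of 8 gene lists, each gene centred on its mean over 12 libraries (vertical axes), in the 4 groups as labelled (horizontal axes); points are libraries, bars the mean and SD of 3. Old WT lies highest for macrophage markers, with replicate 3 above the other libraries, and young AKO highest for oxidative phosphorylation.

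The interaction asks whether the genotype effect differs between ages. Of 15059 genes, Zfp973 alone passed the edgeR test. Its level is uncertain because near-identical copies can share its reads. In all 1408 genes had an unadjusted p under 0.05. After it came Lum, whose genotype effect was -1.61 in old and -0.09 in young mice (-1.52 ± 0.23, adjusted p = 0.241). Among the next were Vasn, a growth factor antagonist (1.63 ± 0.26, adjusted p = 0.241), Cyr61 (2.13 ± 0.35, adjusted p = 0.241), the mitochondrial ribosome gene Mrpl54 (-0.59 ± 0.10, adjusted p = 0.241), the interferon regulator Irf8 (-1.91 ± 0.34, adjusted p = 0.283) and Vegfa (0.84 ± 0.16, adjusted p = 0.415), none of which passed the edgeR threshold. Limma-voom called 0 genes, with 1100 at an unadjusted p under 0.05, and DESeq2 called 57, Zfp973 among them. With the replicate block or limma-trend on FPKM 0 genes were called, and with transcripts not summed 7 others but not Zfp973. Leaving out young AKO replicate 2 gave 4 calls, and young AKO replicate 1, old AKO replicate 1 or old AKO replicate 2 gave 2. For macrophage markers the median difference of the genotype effects was -1.41, old minus young (camera adjusted p = 5.03e-07, adjusted p = 0.653 with an estimated correlation), and for oxidative phosphorylation -0.19 (camera adjusted p = 1.13e-08, adjusted p = 0.653 with an estimated correlation). Fry, which asks whether a list moves on balance, called 0 of 38 lists for the interaction.

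Many genes that were higher in old than in young WT were lower in old AKO than in old WT. Of 2140 genes that rose with age and 779 that fell in old AKO, 707 were the same genes, against 110.7 for independent lists. Of 1319 that fell with age and 122 that rose in old AKO, 90 were shared, against 10.7 for independent lists, and no gene changed in the same direction in both. The counts for independent lists do not allow for the old WT libraries, which both comparisons use, so they do not show how many shared genes those libraries alone would give. Without old AKO replicate 3 the old genotype comparison called 4 genes in all, so few of the 707 and 90 could then be called in both. C1qa, Lyz2, Cd74 and Lum are among the 707 and Hk2 is among the 90. Gpam, lower with age, did not pass in the genotype comparison (0.82 ± 0.24, adjusted p = 0.0695, edgeR). Across genes Pearson's r between both effects was -0.619 (jackknife SE over libraries 0.175; 76.3% of genes with opposite signs), but both use the old WT libraries, and 20 simulations with no effect gave r = -0.497 (SD 0.0247). That r lies within 1 jackknife SE of the observed. The covariance was -0.476 against -0.0979 simulated, a difference of -0.379. The 3 old WT libraries were not split between both effects, so part of the excess may come from the shared controls. Genes are not independent replicates, and the simulations drew each gene on its own, so their SD does not cover genes that move together. With old WT replicate 3 and young WT replicate 1 both left out r was -0.358, nearer 0 than the -0.548 (SD 0.0257) of 20 simulations of that fit. The covariance was then -0.329 against -0.158 simulated.

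**Figure D3:**
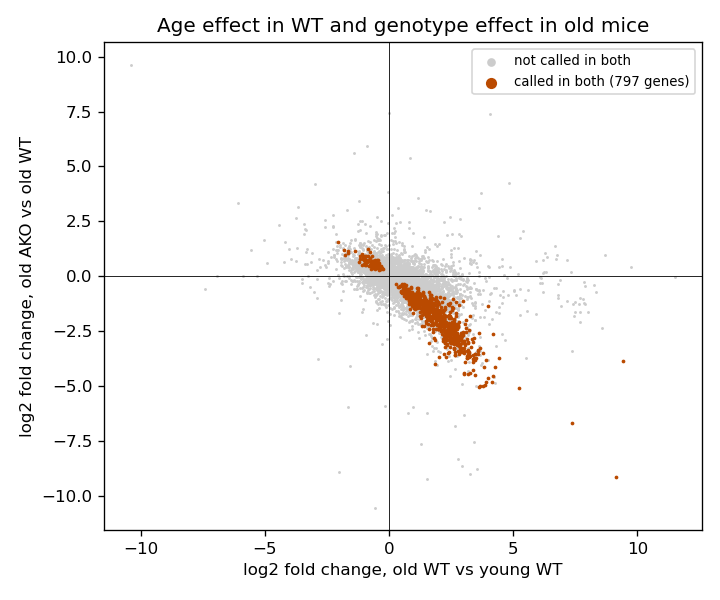
log2 fold change of old WT against young WT (horizontal axis) and of old AKO against old WT (vertical axis) for 15059 genes; orange points are called in both comparisons. The called points lie in the quadrants of opposite direction.

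The genotype effects at both ages, which share no library, were correlated across genes with r = 0.409 (jackknife SE over libraries 0.093), against 0 in simulations with no effect, and a covariance of 0.242. The simulations drew each gene on its own, so they do not show how far r strays from 0 when genes move together. Of 28 and 122 genes higher in AKO, 8 were shared against 0.230 for independent lists: Crtc2, Gsta4, Zfp949, Dusp4, Pik3r2, Zfp467 and the uncertain Morf4l1-ps1 and Morf4l1b. Of 120 and 779 lower genes, 57 were shared, against 6.21 for independent lists, including Cd248, Loxl2 and Fbn1. No gene was called in opposite directions. The counts for independent lists do not allow for genes that move together, or for the shared estimate of the spread. The young comparison called 5 genes in all without young AKO replicate 3, and the old one 4 without old AKO replicate 3. Few of the shared genes could then be called at both ages. Leaving out 1 library gave r between 0.293 (without young WT replicate 2) and 0.410, and with no filter on low counts r was 0.182.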

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

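Some tests were chosen only after the results they bear on were seen. For Crtc2 these were the tests of Kng1 and its neighbours, of other cell types and of transcripts. The others were the macrophage markers against other cell types, all genes called at both ages on chromosome 9, and the Morf4l1 copies. The splits of the libraries were set down before the results they bear on were seen. The test without old WT replicate 3 and that of Gsta4 and Zfp949 as neighbours were set down before they were run. Both name a library or genes picked from these data, so they were not planned before the data were seen.

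Crtc2 was higher in all 6 libraries labelled AKO than in all 6 labelled WT. RNA from cells other than adipocytes is argued against, since none of 13 lists of markers of other cells and tissues rose as much at both ages: the highest value that a list's median log2 difference reached at both ages was 0.397, against 1.66 and 1.89 for Crtc2. That list, of testis germ cells, had a median of 0.397 (SE 0.538 over members) in young and 2.384 in old mice, but its member Prm2 had 1353, 97 and 5 reads in old AKO replicates 1, 2 and 3, where Crtc2 had 9179, 9977 and 9144. Labels reversed between the genotypes stay open. Kng1, a gene that some adipocyte Cre transgenes may carry, had reads in all 6 libraries labelled AKO (2 to 9 each) and 0 in all 6 labelled WT. The exact permutation p was 0.00216 (two-sided), the smallest that 924 arrangements allow. Kng1 was picked after its values were seen, so this p cannot decide, and the labels do not name the Cre line. Its chromosome 16 neighbours Rfc4, Adipoq and Eif4a2 were not called at either age by edgeR. Morf4l1-ps1, further along chromosome 16 (24529314 to 24534472, against 23058300 to 23082078 for Kng1), was called higher in AKO at both ages. Its level is uncertain, since it shares sequence with Morf4l1. Rfc4 was higher in AKO (5.70 against 3.43 CPM in young and 6.14 against 4.92 in old mice). Adipoq (4825 against 4868 in young, 5192 against 3547 in old) and Eif4a2 (469 against 407 and 531 against 364) did not separate in young mice. A more abundant transcript of the recombined allele could also make Crtc2 higher in AKO. It cannot be told apart from the rest, since Crtc2 has 1 transcript and no values per exon here. A biological rise of Crtc2 was not tested.

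Macrophage markers were lower in old AKO than in old WT, with a median log2 difference of -2.22 over 28 members, of which 1, Mmp12, is also in the senescence list. Old WT replicate 3 as the whole source is argued against: without it the median was -1.475, with 17 of 28 members called lower, although 0 of 28 were called over all genes tested without old AKO replicate 1, 2 or 3 (medians -2.303, -2.274 and -2.082, 27 of 28 below 0 each time). A lower share of all cells other than adipocytes stays open: macrophage markers fell further than the markers of 8 other lists together, by -1.365 ± 0.605 (log2, SE over libraries) and by -0.818 ± 0.334 without old WT replicate 3, less than 3 SE in both, and 3 libraries against 3 allow no exact p under 0.1. Fewer macrophages, or macrophages with lower expression, stay open as biological explanations tied to genotype or to how the cells were prepared; none was tested. The labels describe no sort that would remove macrophages.

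Gsta4 and Zfp949, higher in AKO at both ages, lie 10.36 Mb apart on chromosome 9. Chance may suffice for this: a share of 0.2511 of 10000 random draws of 8 tested genes had a pair as close together. Tmod2, Sh3bgrl2 and Plod2, lower in AKO at both ages, lie in the same part (75.6 to 92.5 Mb), and a share of 0.1975 of 10000 draws of 65 genes, as many as were called at both ages, had 5 in a stretch as short. A stretch of another strain linked to the genotype stays open: of all Morf4l1 reads, 19.3 ± 0.32% fell to its copies in the 6 libraries labelled AKO (lowest 18.85) and 12.5 ± 0.55% in the 6 labelled WT (highest 13.16), exact permutation p = 0.00216, two-sided, the smallest possible. Morf4l1 itself lies in this part of chromosome 9 (90091669 to 90114820), while Morf4l1-ps1 and Morf4l1b lie on chromosomes 16 and 19. Its mean was 212 CPM in young AKO against 241 in young WT, and 220 against 245 in old mice. The random draws placed the copies at their own positions, so they do not allow for reads shared with Morf4l1. The copies were picked because they differed, so their share cannot be told apart from a difference in expression. An effect of Crtc2 on these genes was not tested.

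The interaction test by edgeR called 1 gene, Zfp973 (-10.009 on the log2 scale, a fitted value that is no bound since young WT had 0 reads). It did not pass by limma-voom, by limma-trend on FPKM, with the replicate block or with transcripts not summed. Chance is not excluded for Zfp973, since 14 of 100 relabellings called at least as many genes. Its near-identical copy Zfp965 had reads in all 3 young AKO libraries (141 to 159), in 1 old WT library (157) and in old AKO replicates 1 and 3 (155 and 174), and 0 in the others; whether reads were shared between both was not tested. By camera with the preset correlation, the median of old minus young genotype effects was -1.413 for macrophage markers, -1.154 for proliferation, -0.807 for MHC class II genes and -0.744 for inflammatory cytokines. It was -0.388 for cholesterol synthesis, -0.214 for lysosome and autophagy, -0.191 for oxidative phosphorylation and -0.137 for the tricarboxylic acid cycle. It was above 0 for smooth muscle and pericyte markers (0.417), endothelial markers (0.385), adipocyte identity genes (0.287), lipolysis genes (0.224), the tissue dissociation response (0.221) and branched-chain amino acid catabolism (0.087). With each library left out in turn, the camera call was kept in 5 of 12 fits for lysosome and autophagy and in 6 for the tricarboxylic acid cycle. It was kept in 7 for the tissue dissociation response, 8 for branched-chain amino acid catabolism and 9 for cholesterol synthesis. For the endothelial and the smooth muscle lists it was kept in 10, and for the other lists in all 12. With an estimated correlation none of these lists was called.

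With 10 splits of 6 libraries, the splits are too few for a share under 0.05. The real split called 148, 901, 3459 and 2770 genes in the young genotype, old genotype, WT age and AKO age comparisons, the highest other split called 8, 1, 1 and 2, and in each 1 of 10 splits, the real one, reached the real count. For gene lists the real splits called 19, 28, 27 and 19 lists and the highest other splits 15, 23, 22 and 21; 1, 1, 1 and 3 of 10 splits reached the real count. For the interaction, 14 of 100 relabellings called at least as many genes as the real 1, and 45 of 100 at least as many lists as the real 14 (highest other 27), so chance is not excluded for either count. The highest other count of genes, 2169, came when the old labels were exchanged, which adds the genotype effects of both ages instead of subtracting them.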

How the results depend on the processing

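Leaving out old WT replicate 3 and young WT replicate 1 together was chosen after seeing the data; the other alternatives were planned. Counts of called genes are given in the order young genotype, old genotype, WT age, AKO age and interaction (148, 901, 3459, 2770 and 1 as reported). DESeq2 gave 1369, 1911 and, for the interaction, 57. Limma-voom gave 9 in young and 0 for the interaction. Transcripts not summed gave 27, 16, 1640, 1019 and 7. Limma-trend on FPKM gave 17 (5 higher, 12 lower) in young, 0 for the interaction, and within 1.5 times for age but with other shares of higher and lower genes (3386 and 558 in WT, 1715 and 274 in AKO). No pairing of libraries by replicate number was seen across groups (correlations of same-numbered libraries -0.216 to 0.088). These correlations were taken after centring each group of 3 libraries, so they cannot show that there was no pairing. With the replicate block the counts were 54, 12 and, for the interaction, 0. Only the groups compared gave 4, 205 and 1059, with fewer libraries behind the spread. An absolute log2 fold change of at least 1 gave 1701 and 1368 for age. With both libraries that stand apart left out the counts were 861, 519 and, for the interaction, 2. Counts not listed, and those with RLE or other filters, stayed within 1.5 times. Leaving out each library in turn gave 5 to 465, 4 to 1050, 1516 to 4448, 734 to 3779 and 1 to 4 genes, and 18 to 22, 25 to 28, 23 to 28, 18 to 20 and 11 to 16 lists. With an estimated correlation 0 lists were called in each comparison. Fry, which asks whether a list moves on balance, called 6, 19, 23, 17 and 0 of 38 lists in the same order. Crtc2 kept its direction in all alternatives, 1.73 to 2.12 in young and 1.64 to 1.74 in old with a library left out; with only the young groups compared it was 1.90 and no longer past the threshold. The correlation of age and genotype effects ran from -0.641 to -0.457 with a library left out and was -0.358 without both libraries that stand apart. That of the genotype effects ran from 0.293 to 0.410 and was 0.182 with no filter. Of 3364 values of named genes under these alternatives, 2628 kept direction and side of the threshold, 707 lost the call, 13 gained it and 16 reversed, all of them of the uncalled Crtc1, Crtc3 and Adipoq. For Crtc1 in young these were -0.018 with at least 1 CPM in 3 libraries, -0.051 on FPKM and -0.044 without both libraries that stand apart, and -0.038 to 0.145 with a library left out. Crtc3 in young ran from -0.135 to 0.004 with a library left out, and on FPKM the old values were -0.034 for Crtc1 and -0.032 for Crtc3. Adipoq in young was 0.015 by limma-voom, 0.014 with the replicate block, 0.264 without both libraries that stand apart and -0.209 to 0.274 with a library left out. The cause was not tested for any of these.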

Other observations

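Akr1b7, Crisp1 and several sperm genes were read in some libraries and not in others; these genes were singled out after their values were seen, and where their reads come from was not tested. Of 5 measured epididymis markers 0 passed in young AKO against WT (camera adjusted p = 0.734, adjusted p = 0.823 with an estimated correlation) and 1 fell in old (camera adjusted p = 0.0975, adjusted p = 0.284 with an estimated correlation). Akr1b7, an aldo-keto reductase, had 28, 729 and 46 reads in young WT and 200, 3 and 357 in old WT, and 0 in all 6 libraries labelled AKO, at least 260-fold and 199-fold lower against a floor of 3 reads over the group. Crisp1, an epididymal sperm-binding protein, had 271, 406 and 18 reads in young WT and 41, 0 and 135 in old WT, and 0 in all 6 labelled AKO, at least 225-fold and 62.6-fold lower. The sperm chromatin genes Prm1, Prm2, Tnp1 and Tnp2 had 1146, 1353, 687 and 1176 reads in old AKO replicate 1 and at most 97 in any other library, and the sperm tail gene Odf1 304 and at most 28. Of 9 measured testis germ cell markers 0 were called in old AKO against old WT, 9 were above 0 and 5 were higher over the list alone. For this list the camera adjusted p was 0.0148 in old mice (0.423 with an estimated correlation) and 0.521 in young mice.

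With age, mast cell markers were higher in both genotypes. They rose in 4 of 11 members in WT (8 adjusted over the list alone; camera adjusted p = 0.000607, adjusted p = 0.326 with an estimated correlation) and in 5 in AKO (9 over the list alone; camera adjusted p = 0.000384, adjusted p = 0.426 with an estimated correlation), with 3 members at 0 reads in some group. B and plasma cell markers rose in 6 of 16 in WT (11 over the list alone; camera adjusted p = 0.000305, adjusted p = 0.218 with an estimated correlation) and in 3 in AKO (7 over the list alone; camera adjusted p = 0.000412, adjusted p = 0.367 with an estimated correlation). Interferon response genes rose in 8 and fell in 4 of 36 in AKO (11 and 4 over the list alone; camera adjusted p = 0.0781, adjusted p = 0.759 with an estimated correlation), and rose in 6 in WT (6 over the list alone; camera adjusted p = 0.0674, adjusted p = 0.686 with an estimated correlation). Genes of the antioxidant response fell in 5 of 26 in WT (9 lower and 2 higher over the list alone; camera adjusted p = 0.00417, adjusted p = 0.277 with an estimated correlation). The tissue dissociation response, which includes heat shock genes, rose in 8 and fell in 1 of 26 in AKO (8 and 1 over the list alone; camera adjusted p = 0.00264, adjusted p = 0.465 with an estimated correlation).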
